A study of Mus musculus with 9 samples.

How the data were processed

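Circle-seq was run on hearts of C57BL/6J mice in 9 libraries, 3 at embryonic day 18 (E18), 3 at postnatal day 3 (3d) and 3 at 8 weeks (8w), and the labels number the libraries of each stage as biological replicates 1 to 3, with cardiocytes as the cell type. Per the labels' protocols, samples were digested, treated with alkali and purified on columns, circles were amplified with phi29 polymerase, and sonicated product was made into libraries with the NEBNext Ultra II kit. Per the submitters' processing notes, cutadapt 1.9.1, BWA 0.7.12, SAMtools 1.9, bedtools 2.27.1 and an edgeR entry listed as 0.6.9 were used with the builds GRCm38 and mm10. Per the file headers, eccDNAs were identified with Circle-Map. Its version and filters are not given in the sources used here.

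The deposited table gives, per the file headers, the count of split reads of each eccDNA in each library. Beside the counts, the authors deposited log2 values normalized with edgeR, which are linear in the counts on the unlogged scale and equal 3.01 at a count of 0 in every library. The factors these values imply ran from 0.238 (3d replicate 1) to 4.38 (8w replicate 1). They match to 3 decimals those of TMM on the 29028 eccDNAs in at least 2 libraries, with all split reads as library totals. The deposited length column gives the size of the circle in bp, equal to end minus start on every line. The deposited overlap column gives the bp that a circle shares with the annotated gene on its line. The annotation holds protein-coding genes only, with 1 line for each pair of circle and gene, so that 154938 lines hold 149584 distinct circles. The counts were used here, and the log2 values were used only to check them. Coordinates are printed counting from 1, so starts are 1 higher than in the table.

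A circle counted as present with 1 or more split reads. Split reads per library ran from 11377 to 846374, and total reads per library are not given in the sources used here. Shares of a single library carry Wilson 95% intervals. Single values per library were compared over the stages with an exact permutation test of the F statistic over the 280 ways to part 9 libraries into 3 stages, whose smallest p is 0.00357, and between stages with an exact two-sided permutation test of the difference of means, whose smallest p is 0.1. Numbers of circles were tested on the log2 scale. Sharing was tested one-sided on the mean Jaccard index within stages minus that between stages. Chromosome shares, the size classes and the density of lists were adjusted by Benjamini-Hochberg, and the threshold was 0.05 throughout.

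For random placement, 200000 circles per library were drawn with the library's chromosomes and lengths up to 100 kb, outside the first 3 Mb of each chromosome, and set against 21887 RefSeq protein-coding genes of GRCm38.p6. Overlap with gene starts and reciprocal overlap of circles were found with bedtools 2.31.1. No genome sequence was used here, so GC content and mappability were not analysed here.

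Circles in at least 3 libraries (2893) were tested on split reads, and genes on the number of circles overlapping them, with the quasi-likelihood test of edgeR 4.0.16, TMM scaling and 1 fit of all libraries with stage as the only term. The default expression filter of edgeR left 12 genes, so genes with at least 10 circles over the 9 libraries (2174) were used, as set beforehand for that case. DESeq2 1.42.0 was run beside it. The 11 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over all pairs of list and comparison. They were sarcomere, calcium handling and ion channels, cardiac transcription factors, fatty acid oxidation, glycolysis, cell cycle, DNA repair, fibroblast and matrix, endothelium, blood and immune, and long neuronal and fragile-site genes. List density was set against 10000 random lists drawn from the 100 genes nearest in length on each side. Ratios of genes with 1 to 3 circles at a stage carry exact binomial intervals. Other software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

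The comparisons, tests, lists and the rule for named genes were fixed before the data were examined. For each comparison the rule took the 5 genes with the smallest unadjusted p in each direction, since fewer than 5 passed, and the 2 members of each list with the smallest p. It added the 10 genes with the most circles summed over the libraries, the 10 with the most per Mb among genes of at least 20 kb, and, since no circle passed, the 5 circles in the most libraries. A few genes that the rule took are not reported here. The number per Mb was first computed on distinct circles and then on circles summed over libraries, the reading kept, with both lists seen. Size classes, length peaks, random placement, the test of list density between stages, windows of 50 kb, matched lists for camera and the periodicity of lengths were chosen after seeing the data.

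Alternatives tried were a minimum of 2 or 5 reads, thinning to 11377 reads, no Y chromosome, merged overlapping circles, mean log2 length, weighting by reads, assignment by midpoint, circles up to 1 kb, 50% and 90% reciprocal overlap, library totals without TMM, DESeq2, other filters, reads per gene, an estimated correlation, each library left out in turn and the replicate number as a block. Circles of 1 library alone, a minimum of 5 reads, length after thinning, the libraries numbered 1 of 3d and 8w left out together and the permutation test of lists were added after seeing the data.

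The edgeR tests, camera in 1 comparison and the exact permutation F test were tested on simulated data, and the other tests were not. With counts drawn at the dispersion estimated for genes (0.0151), 8-fold higher genes were recovered in 97.2% (3d over E18), 52.9% (8w over 3d) and 51.4% (8w over E18) of cases over 2174 genes, and 8-fold lower genes in 16.1%, 15.2% and 6.67%. At the dispersion estimated for circles (5.169), 0 of the 16-fold and 64-fold changed circles were recovered in any comparison of 2893 circles. At a dispersion of 0.1, 98.0%, 81.6% and 90.7% of the 16-fold higher circles were recovered in the same order, and 39.2%, 19.6% and 15.8% of the 16-fold lower ones. For camera, a 2-fold shift of a list of 15 genes in 8w over E18 was called in 45 of 50 simulations, and a list without a shift in 1. These calls were at an unadjusted camera p under 0.05. Genes were drawn independently and lists at random, so error rates for lists of correlated genes or of genes with many circles were not covered. The exact permutation F test was at or below 0.05 in 5.5% of 2000 simulations with no shift and in 96.1% with the adult libraries shifted by 4 SD.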

Results

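Extrachromosomal circular DNA (eccDNA), closed circles carrying chromosomal sequence, was measured by Circle-seq, an assay that removes linear DNA, copies the remaining circles with phi29 polymerase and sequences the product. The 9 libraries came from hearts of C57BL/6J mice, with 3 libraries at embryonic day 18 (E18), 3 at postnatal day 3 (3d) and 3 at 8 weeks (8w). The labels give heart as the tissue and cardiocytes as the cell type, so whether whole hearts or isolated cells were used is not known, and hearts below stands for either. Split reads, which span the junction where a circle closes, numbered 846374, 63710 and 186129 in E18 replicates 1 to 3. They numbered 310110, 341384 and 665303 in the 3d replicates and 11377, 194280 and 67182 in the 8w replicates. The table listed 149584 distinct circles, from 28 to 9946447 bp long, of which 79 were over 100 kb. A circle counted as present in a library with 1 or more split reads there. Coordinates are those of GRCm38/mm10, and all stage values are means ± SD over 3 libraries. Wilson 95% intervals and floors for a count of 0 cover counting error only, since amplified reads are not independent molecules.

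The series asks to what extent eccDNAs occur at each developmental stage of the mouse heart. Neonatal hearts held 33935 ± 8296 circles per library (SD, n = 3), embryonic hearts 18266 ± 14747 and adult hearts 8432 ± 5613. Each adult library, with 3931, 14721 and 6645 circles, held fewer than each neonatal library, with 32194, 26648 and 42963. The embryonic libraries held 35273, 9039 and 10485 circles and spanned nearly the whole range. Circles with a single split read made up 37.9% of 3d replicate 1 and 60.5% of 8w replicate 1, against 6.21% to 16.7% of the other 7 libraries. The difference over the 3 stages did not pass (exact permutation test of the F statistic on log2 numbers, p = 0.0857). The log2 ratio of means was 0.89 for 3d over E18 (1.86-fold, exact two-sided permutation p = 0.3), -2.01 for 8w over 3d (p = 0.1, against a spread of 1.02, SD) and -1.12 for 8w over E18 (p = 0.4), and 0.1 is the smallest p that 3 against 3 libraries allow. With every library thinned to 11377 split reads, the log2 ratio was -0.54 for 8w over 3d, 0.30 for 3d over E18 and -0.24 for 8w over E18, and 8w replicate 2 held more circles (6985) than 3d replicate 1 (6526). Leaving out single libraries, the 8w over E18 ratio ran from -1.79 to -0.21. The p over the stages was 0.0286 without E18 replicate 1 and 0.0321 without 8w replicate 2 (exact permutation tests).

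Adult hearts held shorter circles than embryonic and neonatal hearts. The median length was 190 ± 123 bp at 8w (SD, n = 3), 368 ± 1.73 bp at E18 and 384 ± 19.1 bp at 3d (exact permutation test over the 3 stages, p = 0.0107). The adult medians were 331, 135 and 103 bp, and those of the other 6 libraries lay between 366 and 405 bp. With 2 or more reads per circle the adult medians were 139, 132 and 100 bp, and the others lay between 363 and 412 bp. The 8w median was lower than that of 3d by a difference of -194 bp and lower than that of E18 by -178 bp (exact two-sided permutation p = 0.1 for both), while 3d minus E18 was 15.7 bp (p = 0.3), and 5.0 to 23.5 bp leaving out single libraries. Weighted by split reads, 8w minus 3d was -327 bp and 3d minus E18 79.0 bp, and after thinning 3d minus E18 was 67.7 bp. The stage p was 0.05, 0.0571 and 0.05 without E18 replicates 1, 2 and 3, and 0.05 without 3d replicate 3 (exact permutation tests).

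**Figure D1:**
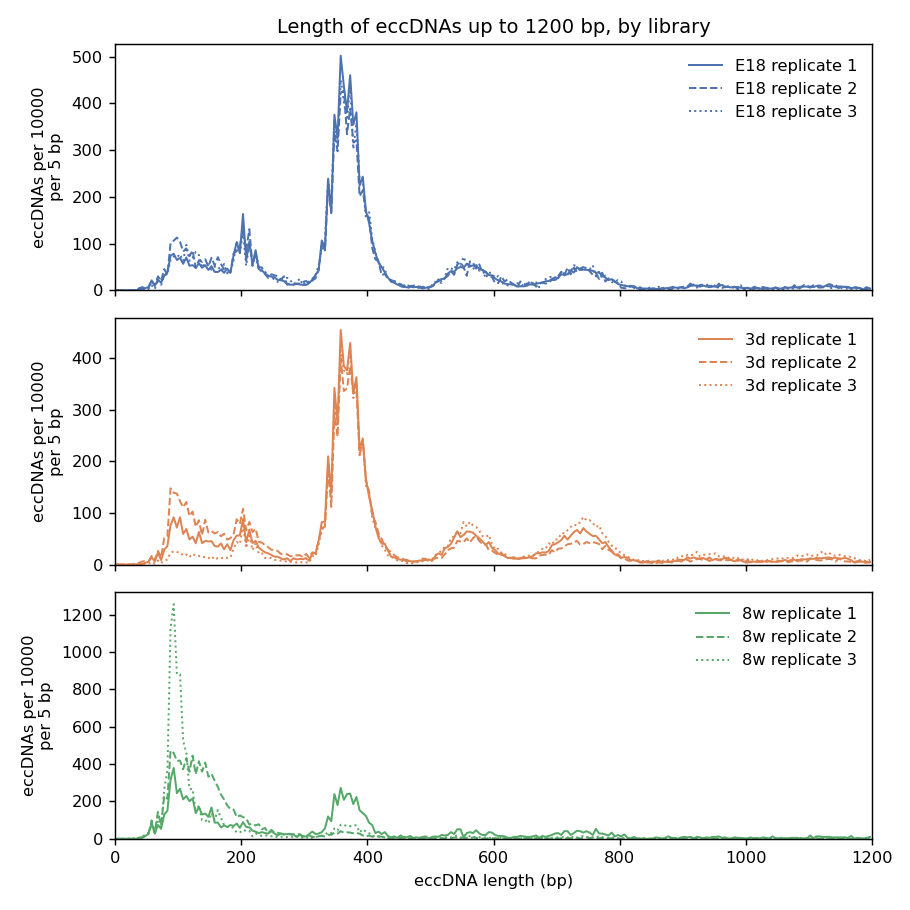
Length of eccDNAs in bp (x axis) against the number per 10000 eccDNAs of the library in bins of 5 bp (y axis, a separate scale for each stage), with 1 line per library. The E18 and 3d libraries peak near 366 bp, and the adult libraries are highest at shorter lengths.

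Circles up to 1 kb made up most of every library. Their share was 95.3 ± 0.646% at E18, 91.4 ± 3.76% at 3d and 97.7 ± 2.19% at 8w (exact permutation p = 0.0143, Benjamini-Hochberg adjusted over 3 classes 0.0214, n = 3). Circles of 1 to 10 kb made up 4.68 ± 0.644% at E18, 8.55 ± 3.76% at 3d and 2.22 ± 2.16% at 8w (exact permutation p = 0.0143, adjusted 0.0214). The p of the 1 to 10 kb share was 0.0643, 0.0607 and 0.0571 without E18 replicates 1, 2 and 3, 0.0821 without 3d replicate 3, and 0.05 without 8w replicate 2 or 3. That of the share up to 1 kb was 0.0643 and 0.0607 without E18 replicates 1 and 2, 0.0821 without 3d replicate 3, and 0.0536 and 0.05 without 8w replicates 2 and 3 (exact permutation tests). Circles above 10 kb were rare, at 0.0492 ± 0.0142%, 0.0678 ± 0.00585% and 0.0355 ± 0.0384%, and the stages did not pass the test (exact permutation p = 0.318), except without 8w replicate 1 (p = 0.0107).

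Within the short range, adult hearts differed in which circles they held. Circles under 250 bp made up 72.9 ± 23.4% of adult circles (SD, n = 3), against 22.8 ± 2.16% at E18 and 17.6 ± 9.70% at 3d (exact permutation p = 0.0179, adjusted over 4 classes 0.0214). By library the share was 46.0% (Wilson 95% interval 44.5 to 47.6%), 89.2% (88.6 to 89.7%) and 83.4% (82.4 to 84.2%) in the adult replicates, and at most 27.4% (26.9 to 27.9%) elsewhere, in 3d replicate 2. The number of such circles, 4033 ± 3031 at E18, 5461 ± 1936 at 3d and 6825 ± 5766 at 8w, did not pass the test (exact permutation p = 0.711). At 11377 split reads per library it was 1274 ± 359, 970.3 ± 811 and 4203 ± 2373 (exact permutation p = 0.0571). Circles of 250 to 450 bp numbered 9497 ± 7976, 15773 ± 3586 and 1030 ± 317 at E18, 3d and 8w (exact permutation p = 0.0107, adjusted 0.0143). Circles over 650 bp numbered 2924 ± 2336, 8893 ± 5139 and 370 ± 176 (exact permutation p = 0.00714, adjusted 0.0143). Counting only circles with 2 or more reads, the adult numbers were 441 ± 290.5 and 86.0 ± 32.5 for these classes (exact permutation p = 0.0107 over the stages for both). At 11377 split reads per library, E18, 3d and 8w held 3113 ± 881, 3340.3 ± 148 and 604 ± 565 of 250 to 450 bp (exact permutation p = 0.0214). Over 650 bp they held 1054 ± 432, 2314 ± 984 and 226 ± 301 (exact permutation p = 0.00714), so the 3d to 8w drop was smaller at equal numbers of split reads. In the smoothed length distribution above 250 bp, the highest peak was at 365 bp at E18, 367 bp at 3d and 366 bp at 8w. Further peaks stood at 557 and 739 bp at E18, 561 and 742 bp at 3d, and 547, 742 and 1121 bp at 8w. These 4 classes were set after the lengths had been seen.

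**Figure D2:**
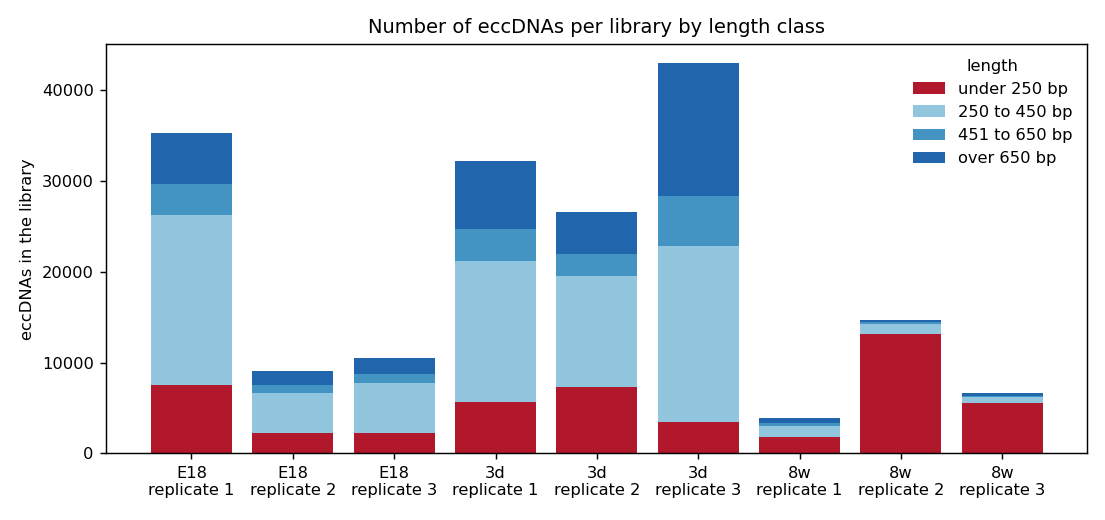
Number of eccDNAs in each library (y axis), stacked by length class, for the 9 libraries (x axis). Each adult bar is shorter than each neonatal bar. Circles under 250 bp number 1810, 13125 and 5539 in the adult bars from left to right. They make up 46.0, 89.2 and 83.4% of these bars, a larger share than in any other library.

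Circles came from every chromosome, and chromosome X gave fewer for its size than any autosome. Per Mb of span, the 9 libraries together gave 33.9 distinct circles on X, 52.5 to 61.9 on the autosomes and 0.495 on Y, which had 45 circles. The labels give no sex. X held 3.78 ± 0.570% of circles at E18, 3.55 ± 0.455% at 3d and 4.58 ± 0.204% at 8w (exact permutation p = 0.0714, adjusted over 21 chromosomes 0.287, n = 3). Chromosome 4 had the smallest p, with 6.21 ± 0.109% at E18, 5.95 ± 0.0541% at 3d and 5.77 ± 0.134% at 8w (exact permutation p = 0.00357, the smallest that 280 partitions can give, adjusted 0.075). 0 of 21 chromosomes passed the adjusted threshold. Across 20 chromosomes without Y, the mean share of circles followed the share of genome span (Pearson r = 0.880, permutation p = 1e-05, which is the smallest they can give, Spearman rho = 0.839, p = 2e-05). Without the 2 chromosomes farthest from the median r was 0.789. The number of distinct circles per Mb showed no such relation to protein-coding genes per Mb (r = 0.189, permutation p = 0.420, rho = 0.187, p = 0.431, and r = 0.319 without 2 chromosomes). These were the only 2 relations across chromosomes that were computed, and chromosomes are not independent replicates.

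Adult hearts held a smaller share of circles in protein-coding genes. The share overlapping a gene was 39.4 ± 0.684% at 8w (SD, n = 3), 42.2 ± 0.953% at E18 and 43.6 ± 0.550% at 3d (exact permutation test over the 3 stages, p = 0.00714). Every adult library, with 40.1% (Wilson 95% interval 38.6 to 41.6%), 39.3% (38.5 to 40.0%) and 38.7% (37.6 to 39.9%), lay below every other library, of which the lowest was E18 replicate 2 with 41.2% (40.1 to 42.2%). The difference was -4.21 percentage points for 8w minus 3d and -2.86 for 8w minus E18 (exact two-sided permutation p = 0.1 for both), and 1.35 for 3d minus E18 (p = 0.2). With RefSeq genes in place of the table's annotation, the share overlapping a protein-coding gene was 43.6% at E18, 45.2% at 3d and 40.6% at 8w. Set against random placement of circles of the same lengths on the same chromosomes, this RefSeq share was 1.12 ± 0.0222 times the random share at E18. It was 1.15 ± 0.0165 times at 3d and 1.04 ± 0.0198 times at 8w (exact permutation p = 0.00714, n = 3). Random placement ignored which sequence can be mapped, and RefSeq protein-coding genes cover 37.9% of the span. Circles within 2 kb of a gene start made up 2.69 ± 0.207%, 2.72 ± 0.112% and 2.41 ± 0.232% at E18, 3d and 8w, and the stages did not pass the test (exact permutation p = 0.164).

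**Figure D3:**
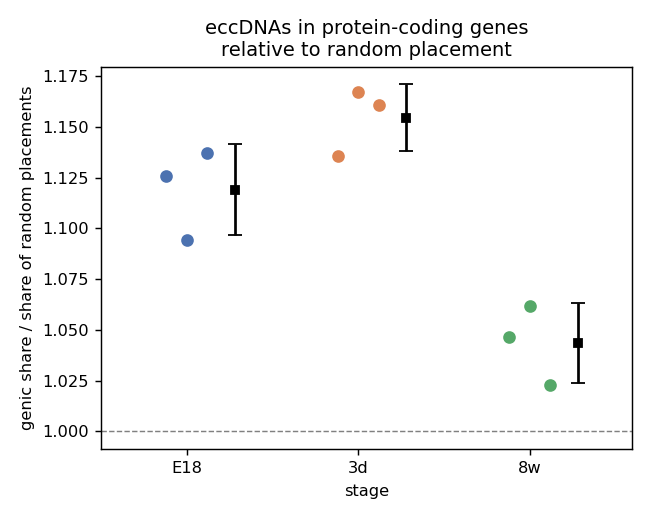
Share of eccDNAs that overlap a RefSeq protein-coding gene divided by the share of randomly placed circles of the same lengths (y axis, which does not start at 0, with a dashed line at 1) for each stage (x axis), with 1 circle per library and the mean ± SD as a square with bars. The adult libraries lie between 1.02 and 1.06, below the other 6, which lie between 1.09 and 1.17.

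Most circles were private to a single heart library. Of the 149584 circles, 120556 (80.6%) were in 1 library, 26135 (17.5%) in 2 and 2893 in 3 or more. A stage's libraries had few in common, as 26 of 53262 circles of E18, 222 of 91322 of 3d and 14 of 24518 of 8w were in all 3 libraries of the stage. Circles of all 3 stages numbered 771, and 130837 were of 1 stage. Among circles with 5 or more reads in some library, 2084 of 117724 (1.77%) had 5 or more reads in 2 or more libraries. Pairs of libraries of the same stage shared 2.89 ± 2.65% of their circles (mean Jaccard index, SD over 9 pairs) and pairs of different stages 1.95 ± 1.5% (27 pairs), a difference of 0.937 percentage points (exact permutation test, one-sided p = 0.0321). Counting only circles with 2 or more reads the difference was 0.426 points (p = 0.00714), and with 5 or more reads 0.0988 points, 0.250% against 0.152% (p = 0.0143, exact permutation tests). The p with all circles was 0.0607, 0.279 and 0.393 without 3d replicates 1, 2 and 3, so the difference rested on the neonatal libraries. Among them, 3d replicate 1 shared 6.74% with 3d replicate 2 and 8.18% with 3d replicate 3 (Jaccard index), against 1.92% for replicates 2 and 3. No other pair of the same stage was above 2.23%, while 3d replicate 1 also shared 7.95% with E18 replicate 1. The difference with all circles therefore leaned on pairs of 1 library, which shared more with libraries of every stage. Leaving out single libraries, it ran from 0.154 to 1.56 percentage points. Of the circles with 5 or more reads in another library, 11.8 to 13.3% were also in 3d replicate 1, whatever the stage of the other library, against 0.786 to 4.91% for the remaining 8 libraries.

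**Figure D4:**
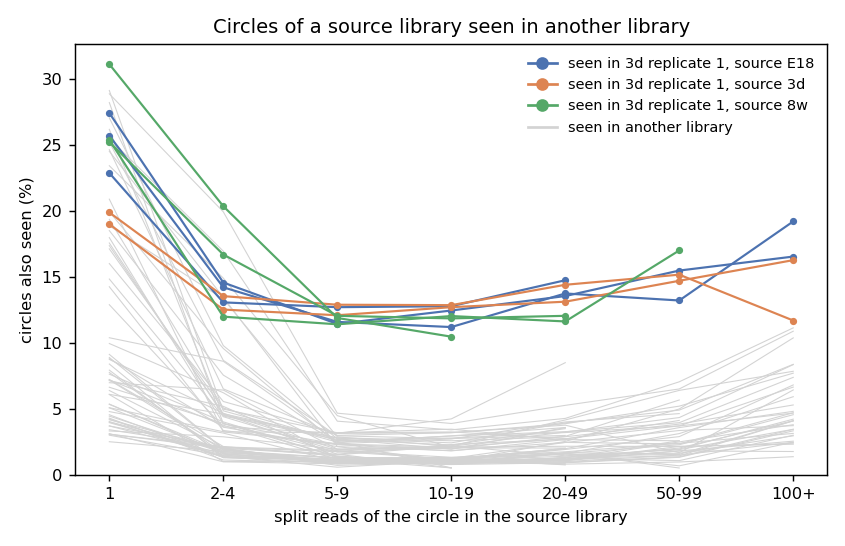
Share of the circles of a source library that are also seen in another library (y axis, %), by the circle's split reads in the source library (x axis), for every pair of libraries, where the class holds at least 100 circles. Coloured lines are circles seen in 3d replicate 1, by the stage of the source library, and lie above the grey lines of the other pairs from 5 reads on.

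The 5 most widely shared circles, with ties broken by summed split reads, lay outside the protein-coding genes of the table. A circle of 359 bp on chromosome 4 (136870272 to 136870630) was in all 9 libraries with 202 split reads, of which 144 came from E18 replicate 3. Circles of 705 bp on chromosome 10 (81353448 to 81354152, 52 reads) and 805 bp on chromosome 1 (39756053 to 39756857, 24 reads) were also in all 9. The 359 bp circle had a single read in 8w replicate 3. That of 705 bp had a single read in E18 replicate 3, 3d replicate 2 and 8w replicate 2. That of 805 bp had a single read in E18 replicate 2, 3d replicate 3 and 8w replicates 2 and 3. A circle of 1332 bp on chromosome 9 (111081687 to 111083018, 60 reads) and 1 of 137 bp on chromosome 4 (84841583 to 84841719, 42 reads) were in 8. That of 1332 bp had a single read in E18 replicates 1 and 2 and 8w replicate 2. Presence by a single read may be background counted at coordinates called in other libraries, which was not settled here.

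No single circle passed the edgeR test between stages. In simulations at the dispersion estimated for circles, 0 of the 64-fold changed circles were recovered, so this result does not show that circles are unchanged. Of the 2893 circles in 3 or more libraries, edgeR called 0 in 3d over E18, 0 in 8w over 3d and 0 in 8w over E18, with 126, 21 and 7 at an unadjusted p under 0.05. The last counts depended on scaling and on single libraries, and were 193, 55 and 134 of 2893 with library totals alone. Leaving out single libraries also changed which circles were tested. There were 8 of 1649 for 3d over E18 without E18 replicate 1 and 147 of 1955 for 8w over 3d without 3d replicate 2. Without 3d replicate 1 only 892 circles were tested, so most of the 2893 reached 3 libraries only through it. Of its circles with 5 or more reads in another library, 67.5% had 1 read in 3d replicate 1. DESeq2 called 2, 3 and 2 of 2558 circles with an adjusted p (13, 11 and 6 at an unadjusted p under 0.05), and these calls fell on 4 circles, named here after their values were seen. They were a circle in Arl5a (chromosome 2, 52406379 to 52407290), which had 61 of its reads in 3d replicate 1, and a circle in Alpk1 (chromosome 3, 127756423 to 127756811), which had 53 in E18 replicate 3. The others lay in no gene of the table, on chromosome 3 (131484307 to 131484569, 57 reads in E18 replicate 3) and chromosome 5 (97345003 to 97345405, 59 reads in 3d replicate 1). Each owed its reads to 1 library, with at most 2 reads in any other.

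For genes, the circles overlapping each gene were counted per library, without weighting by reads. Summed over the libraries of a stage, circles numbered 54797 at E18, 101805 at 3d and 25297 at 8w, so that equal counts are not equal frequencies. Of 14085 genes with a circle, 2174 had 10 or more summed over the libraries and were tested, with a median of 16. Fitted log2 changes carried a common shift from the scaling of libraries by TMM (trimmed mean of M values), as the median of all genes was 0.26 for 3d over E18, -0.79 for 8w over 3d and -0.57 for 8w over E18. With library totals alone those medians were 0.06, -0.06 and -0.05. Log2 changes of genes are therefore given relative to the median of all genes. Their SE and p, and so the choice of genes by p, come from the edgeR test of the unshifted change against 0. A relative change set against its SE does not give the printed p. Unshifted changes in 8w over 3d were below 0 for 1737 of 2174 genes with TMM and for 1113 with library totals alone. The table's gene models, used for all counts, differ from RefSeq's for some named genes. Cx3cr1 spans 167 kb in the table and 19.6 kb in RefSeq, with 10 and 2 distinct circles, and Smyd1 108 and 48.3 kb, with 8 and 6. Slc35f3 (96.9 and 258 kb), Rad51b (211 and 551 kb), Slc8a1 (261 and 365 kb), Dlg2 (1356 and 1973 kb) and Sp110 (21.9 and 40.1 kb) are shorter in the table. A gene with no circle at a stage was set against a floor of 3 circles over that stage, which is 0.548, 0.295 and 1.19 per 10000 circles at E18, 3d and 8w. Folds given as at least rest on that floor and take the count of the other stage as exact. They are therefore not confidence bounds, and counting error of the other stage may leave room for a smaller change or none.

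From E18 to 3d, the genes with the smallest p included Cald1, Rbfox2, Map2k5, Mgmt and Pcnx on the higher side and Slc35f3, Ankhd1, Adamts2, Nyap2 and Rabgap1l on the lower side. Cald1, which encodes the actin-binding protein caldesmon (ENSMUSG00000029761, chromosome 6, 34598500 to 34775473), had 0 circles at E18 and 17 at 3d, or 1.66 ± 0.184 per 10000 (SD, n = 3), at least 3.05-fold higher. Rbfox2, a splicing regulator (ENSMUSG00000033565, chromosome 15, 77078990 to 77307053), had 0 and 14, at least 2.51-fold higher, and Pcnx 0 and 12, at least 2.15-fold higher. Map2k5, a kinase of a MAP kinase pathway, had 3 circles at E18 and 27 at 3d (ratio 4.84, 95% counting interval 1.49 to 24.95). Mgmt, which removes alkyl groups from guanine, had 2 and 23 (ratio 6.19, interval 1.53 to 54.2). None of these changes passed adjustment over all genes (adjusted p = 0.757 for each of them in edgeR).

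On the lower side of 3d over E18, Rabgap1l had 23 circles at E18 and 16 at 3d (relative log2 change -1.44 ± 0.528, SE), and Adamts2, a procollagen-processing protease, 13 and 6 (-1.98 ± 0.740). Slc35f3 had 10 and 3 circles (ratio 0.161, interval 0.0286 to 0.627), Nyap2 9 and 3 (0.179, 0.0312 to 0.719) and Ankhd1 8 and 2 (0.135, 0.0139 to 0.674). Their adjusted p was 0.956 to 0.989 in edgeR.

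By fixed list, 0 members passed over all genes in 3d over E18. Of 7 cardiac transcription factors 5 lay above the median of all genes. Gata4, an early regulator of heart muscle (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692), had 0 circles at E18, 11 at 3d and 0 at 8w, at least 1.97-fold higher at 3d than at E18. The 3d replicates had 3, 7 and 1 of them (1.26 ± 1.23 per 10000), so this fold leans on 1 library. Gata4 was the 1 factor that passed when adjusted over the list alone, by an edgeR p of the unshifted change (median of all genes 0.26). Prdm16 had 0.919 ± 0.956 circles per 10000 at E18 and 1.94 ± 0.130 at 3d. Of 14 genes of calcium handling and ion channels 10 lay above the median, among them the calcium-release channel gene Itpr2 (0.473 ± 0.818 and 2.41 ± 0.478 per 10000) and the potassium channel gene Kcnq1 (0.919 ± 0.956 and 2.13 ± 0.230). Of 7 DNA repair genes 3 lay above, with the helicase gene Wrn at 1 and 12 circles (ratio 6.46, interval 0.956 to 276) and the mismatch repair gene Msh3 at 10 and 5 (relative log2 change -1.87 ± 0.809, SE). The 3 sarcomere genes all lay below, with Nebl at 2.40 ± 0.794 and 2.16 ± 0.842 per 10000 and Neb at 2.67 ± 0.998 and 1.81 ± 1.24.

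Of the other lists in 3d over E18, 1 of 3 fatty acid oxidation genes lay above the median of all genes, with Ppargc1b above (1 circle at E18 and 7 at 3d) and Esrrg below (17 and 32). Of 4 fibroblast and matrix genes 3 lay above, among them Col5a1 (3 and 13) and Fbn1 (5 and 12). Of 7 endothelial genes 2 lay above, with Erg above (4 and 11) and Tek below (6 and 5). Of 12 blood and immune genes 6 lay above, with Ptprc above (1 and 8) and the long table model of Cx3cr1 below (7 and 6). Of 29 long neuronal and fragile-site genes 15 lay above with TMM and 12 with library totals alone (Wwox 19 and 56, Auts2 24 and 65). Hk1 of glycolysis had 4 and 5 circles, and the cell cycle genes Cdk6 and Rb1 8 and 10 and 5 and 7. In all, edgeR called 0 of 2174 genes in 3d over E18 (85 at an unadjusted p under 0.05) and DESeq2 0 (15 at an unadjusted p under 0.05). The 85 became 138 of 1685 tested genes without E18 replicate 1 and 53 of 1672 without 3d replicate 1. With split reads in place of circles edgeR called 1 of 2445 genes, Wdr44 on chromosome X, in each of the 3 comparisons. Its 3d replicates had 1, 38 and 8 reads, the 38 from 1 circle, and its E18 replicates 0, 0 and 1. In 8w replicate 1 it had 252 reads from 2 circles.

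From 3d to 8w, several genes with 20 or more neonatal circles had none in adult hearts. Bach2, a transcription factor of lymphocytes (ENSMUSG00000040270, chromosome 4, 32238804 to 32586108), had 24 circles at 3d, or 2.30 ± 0.936 per 10000 (SD, n = 3), and 0 at 8w, at least 1.99-fold lower. Sncaip had 22 and 0 (at least 1.82-fold lower) and Tmem108 20 and 0 (at least 1.66-fold lower). Tenm4 had 41 and 2 (ratio 0.196, 95% counting interval 0.0230 to 0.756), and the dynamin gene Dnm3 29 and 1 (ratio 0.139, interval 0.0034 to 0.837). On the higher side stood Thsd7b (ENSMUSG00000042581, chromosome 1, 129273302 to 130219278), with 2.59 ± 0.639 circles per 10000 at 3d and 9.69 ± 2.70 at 8w (relative log2 change 1.95 ± 0.503, SE). None of these passed (adjusted p = 0.386 for each of them in edgeR).

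With library totals in place of TMM, Thsd7b was the 1 gene that edgeR called in 8w over 3d (log2 1.95, adjusted p = 0.0140), and it was higher in each of the 3 adult libraries than in each neonatal library per 10000 circles. Phactr2, Ncoa7 and Arhgef10l each had 5 circles at 3d and 7 at 8w, with a relative log2 change of 2.57 in each (SE 0.898 to 0.905), though 6 of the 7 for Ncoa7 were in 8w replicate 2 and 5 of the 7 for Phactr2 in 8w replicate 3. Lin28b, an RNA-binding protein gene of early development, had 2 and 5 (ratio 10.1, interval 1.65 to 106). In all, 0 of 2174 genes passed in 8w over 3d by edgeR (263 at an unadjusted p under 0.05) and 0 by DESeq2 (81 at an unadjusted p under 0.05). The 263 fell to 97 with library totals alone, and to 117 of 2116 and 105 of 2099 tested genes without 8w replicates 1 and 3.

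By fixed list, 0 members passed over all genes in 8w over 3d, and 3 lists each had 1 member that passed when adjusted over the list alone. These were Meis2 among the cardiac transcription factors (16 circles at 3d and 0 at 8w, at least 1.33-fold lower), Neb among the sarcomere genes (20 and 1, ratio 0.201, interval 0.0049 to 1.26) and Esrrg, an activator of oxidative metabolism, in fatty acid oxidation (32 and 3, ratio 0.377, interval 0.0739 to 1.21). The edgeR p of these members tests the unshifted change, so it takes in the common shift of -0.79 from TMM. Sarcomere and fatty acid oxidation had only 3 tested members each, and the intervals of Neb and Esrrg include 1. Of 7 cardiac transcription factors 4 lay above the median of all genes, and Gata4 lay below (11 circles at 3d and 0 at 8w). Of 14 genes of calcium handling and ion channels 7 lay above. Below it, the sodium-calcium exchanger gene Slc8a1 had 16 and 0 (at least 1.33-fold lower) and Kcnq1 22 and 2 (ratio 0.366, interval 0.0417 to 1.49). Of 7 DNA repair genes 6 lay above, with Rad51b at 8 and 5 circles (relative log2 change 1.47 ± 0.905, SE), while Rad18 lay below (10 and 0).

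Of the other lists in 8w over 3d, 1 of 3 sarcomere genes lay above the median of all genes (Nebl 22 circles at 3d and 5 at 8w) and 2 of 3 fatty acid oxidation genes, Ppargc1b (7 and 3) among them. Above it lay 2 of 4 fibroblast and matrix genes, 4 of 7 endothelial genes and 6 of 12 blood and immune genes. Below it lay Fbn1 (12 and 1) and Ltbp1 (17 and 3) of the matrix, Tek (5 and 0) and Vwf (8 and 1) of the endothelium, and Plcg2 (12 and 1) and the long table model of Cx3cr1 (6 and 0) of the immune genes. Of 29 long neuronal and fragile-site genes 15 lay above. Below it, the polarity gene Pard3 had 26 and 1 circles (ratio 0.155, interval 0.0038 to 0.942), and Csmd1 8.06 ± 2.12 per 10000 at 3d and 4.04 ± 3.50 at 8w. Hk1, Cdk6 and Rb1 had 5, 10 and 7 circles at 3d and 1 each at 8w.

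From E18 to 8w, Nedd4l, Tenm4, Atg10 and Syn3 were among the genes with the smallest p on the lower side. Nedd4l, a ubiquitin ligase gene (ENSMUSG00000024589, chromosome 18, 64887756 to 65217826), had 22 circles at E18, or 4.02 ± 0.726 per 10000 (SD, n = 3), and 1 at 8w (ratio 0.0985, 95% counting interval 0.0024 to 0.609). Tenm4 had 25 and 2 (ratio 0.173, interval 0.0199 to 0.695). The autophagy gene Atg10 and the synapsin gene Syn3 had 12 and 0 each, at least 1.85-fold lower, though 10 of the 12 for Syn3 were in E18 replicate 1. On the higher side, A230046K03Rik (ENSMUSG00000034560, chromosome 10, 83543941 to 83596469) had 0 circles at E18 and 5 at 8w, at least 3.61-fold higher, and all 5 were in 1 adult library. Dclk2 had 0 and 4, at least 2.89-fold higher, over 3 adult libraries. Ncoa7 had 2 and 7 (ratio 7.58, interval 1.44 to 74.8), with 6 of the 7 in 1 adult library, and Cd109 and Lmbrd1 had 0 and 3 each, in 1 adult library. None of these passed (adjusted p = 0.621 for each of them in edgeR), and edgeR called 0 of 2174 genes (153 at an unadjusted p under 0.05) and DESeq2 0 (55 at an unadjusted p under 0.05). The 153 fell to 91 of 1685 tested genes without E18 replicate 1 and to 81 of 2099 without 8w replicate 3.

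By fixed list, 0 members passed in 8w over E18, over all genes or adjusted over the list alone. Of 7 cardiac transcription factors 5 lay above the median of all genes, with the muscle methyltransferase gene Smyd1 above (1 circle at E18 and 4 at 8w) and Meis2 below (9 and 0, at least 1.39-fold lower). Of 14 genes of calcium handling and ion channels 6 lay above, and Slc8a1 lay below (6 and 0). Of 3 sarcomere genes 1 lay above, while Neb (13 and 1, ratio 0.167, interval 0.0039 to 1.11) and the titin gene Ttn (4 and 1) lay below. Of 3 fatty acid oxidation genes 2 lay above, with Ppargc1b above (1 and 3) and Esrrg below (17 and 3). Of 7 DNA repair genes 5 lay above, with Wrn above (1 and 3) and Msh3 below (10 and 2). Of 4 fibroblast and matrix genes 2 lay above, and Ltbp1 (10 and 3) and Fbn1 (5 and 1) lay below. Of 7 endothelial genes 4 lay above, with Erg above (4 and 7) and the angiopoietin receptor gene Tek below (6 and 0). Of 12 blood and immune genes 5 lay above, while Arhgap15 (18 and 4) and the long table model of Cx3cr1, most of it outside the RefSeq gene, lay below (7 and 0, at least 1.08-fold lower). Of 29 long neuronal and fragile-site genes 17 lay above, and Cntnap2, which lay below, had 10.5 ± 3.17 circles per 10000 at E18 and 5.63 ± 1.73 at 8w. Hk1, Cdk6 and Rb1 had 4, 8 and 5 circles at E18 and 1 each at 8w.

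As sets, the lists were compared with all other genes by camera in limma, with its preset correlation of 0.01. Of 27 pairs of list and comparison, 1 passed. The long neuronal and fragile-site genes were called lower in 8w over 3d (adjusted p = 0.0139), but the adjusted p was 0.981 with an estimated correlation, and by fry, which tests a list against no change and not against other genes, it was 0.263. Of the 29 members 27 had a fitted log2 change below 0, though 15 lay above and 14 below the median of all genes, and 8 had an unadjusted p under 0.05. The list's median of -0.71 lay above that of all genes, -0.79, and its mean of -0.80 below it, so median and test differed in sign. With library totals alone the camera p was 0.686 in the other direction, and 16 of 29 members lay above the median.

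The call on the long genes was lost without any 1 of the libraries other than 8w replicate 2, with adjusted p between 0.0691 and 0.915 by camera in limma. Without 8w replicate 2 the list was called lower in 8w over 3d (adjusted p = 0.00575) and in 8w over E18 (adjusted p = 0.0130). With circles of 1 library alone it was called in the same 2 comparisons (adjusted p = 0.000129 and 0.00326), in an alternative added after the data were seen. With all libraries and circles, adjusted camera p for the other 2 comparisons of this list was 0.644 (3d over E18) and 0.194 (8w over E18). For the other lists with 3 or more tested members it was 0.313 to 0.644 for sarcomere, 0.313 to 0.697 for calcium handling and ion channels, 0.483 to 0.730 for cardiac transcription factors and 0.976 for fatty acid oxidation. It was 0.644 to 0.976 for DNA repair, for fibroblast and matrix and for endothelium, and 0.976 for blood and immune genes. With an estimated correlation 0 of 27 pairs passed, and fry called 0 in 1 direction and 0 in either direction after adjustment. The median or mean of a list and its camera direction, each taken relative to all genes, also differed in sign in 13 of the other pairs, none of which passed.

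The number of circles per Mb of the fixed lists was set against that of random lists of like gene length, with no adjustment over the 11 lists. Fatty acid oxidation genes had 5.58 circles per Mb and 10000 circles over the 9 libraries, at percentile 98.0 of 10000 lists matched on gene length (median 4.29), and endothelial genes 5.29 (percentile 93.8). Calcium handling and ion channel genes had 3.73, at percentile 4.74 of their matched lists (median 4.21), and the long neuronal and fragile-site genes 3.78 (percentile 13.1). The other lists stood at percentiles 73.3 (sarcomere), 59.3 (cardiac transcription factors), 21.8 (glycolysis), 78.0 (cell cycle), 83.2 (DNA repair), 65.8 (fibroblast and matrix) and 82.5 (blood and immune). Between stages, 0 of 11 lists differed in this density (exact permutation test, smallest adjusted p = 0.836, n = 3). Glycolysis and cell cycle genes had too few tested members for camera.

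Long genes held the most circles. Across 21887 RefSeq protein-coding genes, the number of circles followed gene length (Spearman rho = 0.778 across genes, which are not independent replicates), and 64.4% of the genes had at least 1. In the longest of 10 length classes 99.8% had one, but per Mb the 6 longest classes held about as many, 64.6 to 70.3 distinct circles, with 65.5 in the longest. The 2 shortest classes held 254 and 112 per Mb, where a circle that overlaps a short gene in part counts in full. The table's highest sums over the 9 libraries were 371 circles for Gm20388, 244 for Fgfr2, 173 for Ptprd, 155 for Macrod2, 144 for Cntnap2, 135 for Csmd1, 134 for Arfip1, 130 for Pcdh15, 121 for Dlg2 and 120 for the dystrophin gene Dmd. For some genes the table's model differed from RefSeq's. Gm20388 spans 4435 kb in the table. Fgfr2 spans 2961 kb in the table and 104 kb in RefSeq, with 198 and 9 distinct circles, and Arfip1 1391 and 86.7 kb, with 110 and 7.

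Among genes of at least 20 kb, the highest numbers per Mb were 547 for Sp110, 503 for Sfi1, 497 for Cdc7, 450 for Fam115c, 444 for Prkar1a, 441 for Mkrn1, 431 for Mep1b, 422 for Coq7, 400.2 for Gpt2 and 397 for Mroh2a. These rest on 9 to 31 circles per gene summed over the 9 libraries. Sfi1, a centrosome gene with 31, had 2.16 ± 0.723 circles per 10000 at E18, 1.54 ± 1.11 at 3d and 3.50 ± 3.58 at 8w (SD, n = 3). Cdc7, a kinase gene of replication initiation, had 5 distinct circles, and Coq7, of ubiquinone synthesis, had 3.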

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

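Chosen only after the data were seen were the settings with circles of 1 library alone, a minimum of 5 reads, length after thinning, the libraries numbered 1 of 3d and 8w left out together and the permutation test of lists. Apart from leaving out single libraries, 123 pairs of main result and alternative were counted as the same. Another 6 lost the threshold or calls, 8 gained them and 5 moved beyond the replicate spread. A test counted as the same on the same side of the threshold, and a stage difference within the replicate spread, whatever its sign. Numbers of calls counted as the same where they stayed alike, mostly at 0. Leaving out single libraries, 180 were counted as the same, 15 lost the threshold or calls and 3 gained them, and none of these changed sign. Among differences that were not called, 3d minus E18 of the share near gene starts ran from -0.0922 to 0.0959 points (-0.00142 with circles up to 1 kb) and 8w minus E18 of the share above 10 kb from -0.0342 to 0.00400. For each changed result below the cause was not tested.

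For the number of circles, 8w over 3d moved to -0.54 (log2) with libraries thinned to the smallest total, and the permutation p over the stages ran from 0.0286 to 0.171 leaving out single libraries. For length, 3d minus E18 was 58.3 bp by mean log2 length, 79.0 bp weighted by reads and 67.7 bp after thinning, and 8w minus 3d was -327 bp weighted by reads. Its permutation p ran from 0.0107 to 0.0571 leaving out single libraries. The one-sided permutation p of sharing ran from 0.00357 to 0.393 leaving out single libraries and was 0.143 without both doubted libraries, the 3d and 8w libraries numbered 1. Without those 2 libraries p was 0.295 for number, 0.0286 for length and 0.0190 for the genic share (permutation tests).

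DESeq2 called 2, 3 and 2 circles (3d over E18, 8w over 3d, 8w over E18). With library totals alone 1 gene was called in 8w over 3d, and with reads in place of circles 1 gene in each of the 3 comparisons. Pairs of list and comparison called were 0 with an estimated correlation, 0 with reads in place of circles, 0 with library totals alone, 0 without the doubted libraries, 0 by exact permutation over the stages and 2 with circles of 1 library only, and from 0 to 2 leaving out single libraries.

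With the replicate number as a block, p was 0.222 for number and 0.0278 for length (permutation within the block), edgeR called 0 circles and 0 genes in each comparison, and 1 list was called. Gene counts showed no pairing of the libraries by replicate number. The correlation of libraries of the same number ran from -0.0443 to 0.010 and of others from -0.0274 to 0.0662, and 0 of 9 libraries were closest to one of their own number. With a median of 16 circles per tested gene over the 9 libraries, counting error may hide a pairing, so a shared batch is not excluded. For single circles, simulations at a dispersion of 0.1 recovered 98.0, 81.6 and 90.7% of 16-fold higher and 39.2, 19.6 and 15.8% of 16-fold lower ones, and none at the estimated 5.169. Depth was not varied in them.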

Other observations

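The tests below were chosen only after their results had been seen, except that of lists matched on the number of circles per gene. The lengths of short circles had a period near the turn of the DNA helix. Between 80 and 239 bp, the best period was 11.2, 11.2 and 11.2 bp in the E18 replicates, 11.1, 11.2 and 10.1 bp at 3d and 10.3, 10.7 and 10.5 bp at 8w. The period accounted for 19.4 to 31.7% of the variance left after smoothing by library, above the highest of 1000 draws from the smoothed counts in each, which ran from 11.4 to 14.7%. No test of a difference in period between stages was made.

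Windows of 50 kb held 2.75 distinct circles on average, and the windows below were picked by their counts, with no test of how dense windows would be by chance. The densest window (chromosome 1, 88250001 to 88300000), which holds parts of Hjurp, a chaperone gene of centromeric histone, and of Mroh2a, had 17 distinct circles over 8 libraries. The next, at Npas2, a clock transcription factor gene (chromosome 1, 39300001 to 39350000), had 14 over 6 libraries. A window at Sncaip (chromosome 18, 52800001 to 52850000), named for its pattern after the values were seen, had 12, with 6, 3 and 4 in the 3d replicates and 0 in each 8w replicate.

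Circles under 250 bp made up 46.0, 89.2 and 83.4% of the adult replicates, a larger share than in any other library. A difference in depth does not account for this as a whole, since after thinning the lowest adult library stood 18.878 percentage points above the highest other library. Nor do weakly supported calls, since among circles with 5 or more reads the gap was 56.628 points, with 85.7, 94.1 and 97.0% in the adult replicates. The adult stage and the handling of the adult libraries cannot be told apart, because the labels give no batch. The number of batches known to hold more than 1 stage is thus 0. A shorter circle population in adult hearts may therefore be the source, or the digestion and purification of those libraries may be.

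Of the circles with 5 or more reads in another library, 3d replicate 1 held about an eighth, whichever the library. Of those with 1 read it held 19.003 to 31.1%. Carry-over of reads in proportion to their number would raise the share at least 3 times from circles with 5 to 9 reads to those with 100 or more, and the ratio was 1.3391 ± 0.316 (SD over 4 libraries), below 3 though within 1 SD of the bound of 1.5 set for excluding it. Circles recurring because of the stage would favour the other 3d libraries, yet the share seen of them (13.02%) was 1.053 times that of E18 and 8w (12.4%). Background reads counted at coordinates called elsewhere may be a source and stay open. Circles with 1 read were 11.3553 times as frequent among shared as among private circles (67.5% against 5.94%), which met the value set for this explanation. The other 8 libraries had ratios of 8.12 to 35.2, so a high ratio is not particular to 3d replicate 1 and the test cannot decide. A condition that 3d replicate 1 exceed the ratios of the others was added after these were seen.

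The long neuronal and fragile-site genes were called lower in 8w over 3d by camera. The number of circles per gene may account for the call, since 6.4% of 1000 lists matched on it gave a camera p as small in the same direction and 662 of them were lower at p under 0.05. The members had a median of 87 circles, against 16 for all tested genes. Scaling by TMM may contribute too, since with library totals only the camera p was 0.6861. A difference between neonatal and adult hearts stays open. The list had 3.95 ± 0.272 circles per Mb and 10000 circles at 3d and 3.52 ± 0.501 at 8w. The stages did not pass the test of this density (exact permutation p = 0.343, adjusted over the lists 0.836).

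For gene tests and tests of single circles in the 3 comparisons, all 10 of 10 splits of the 6 libraries gave as many calls as the real value of 0, and the highest other was 0. For gene lists in 3d over E18 the real value was 0 and the highest other 0, with 10 of 10 splits as large. In 8w over 3d the real value was 1 and the highest other 1, with 4 of 10 splits as large, and in 8w over E18 the real value was 0 and the highest other 1, with 10 of 10. Splits of 3 against 3 are too few for a share under 0.05, and a real value of 0 is met by every split whatever the data. For chromosome shares the real value was 0, so that all 280 of 280 partitions gave as many by construction, and the highest other was 2, which says nothing about chance.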
